A study of Glycine max with 16 samples.

How the data were processed

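Small RNA libraries were made from laser-captured cells of soybean seeds of 1.7 to 2.5 mm at the heart stage. Per the labels, seeds were fixed in ethanol and acetic acid, embedded in paraffin and sectioned, total RNA was isolated from each captured subregion, and libraries were built with the Illumina TruSeq Small RNA kit with 15 PCR cycles and a gel size selection. The labels give 250 ng of total RNA per library, except for 50 ng for the endothelium and suspensor. No molecular identifiers were used, so PCR copies of a molecule cannot be told from other molecules, and every interval and floor covers counting error only.

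The deposited files give, for each library, every distinct sequence of 18 to 26 nt with its number of reads, as counts that the authors did not normalise. Bowtie is named in the processing notes without its version, role or genome build, and adapter removal and filters are not stated, so reads that the authors may have removed cannot be known. 8 of the 16 files (endothelium, epidermis and suspensor 1 and 2, inner integument 1 and hilum 2) have a header line and 8 do not. The totals are of reads of 18 to 26 nt, not of all reads sequenced.

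Groups were the 8 subregions of the labels with 2 libraries each. The labels do not tie libraries of the same replicate number to the same plants. Residuals paired little by number: over 28 pairs of subregions their correlations across sequences ran from -0.0707 to 0.143, with a median of 0.0058. The highest were 0.143 (embryo proper and outer integument), 0.122 (hilum and outer integument) and 0.113 (embryo proper and inner integument). The main test had no replicate block, which was tried as an alternative. The tables were joined by sequence, giving 7975066 distinct sequences over the 16 libraries, of which 192177 had at least 20 reads in all. Sequences of 19 to 24 nt counted for a microRNA family when they started within 1 base of a listed mature sequence and overlapped it by at least 18 bases with at most 2 mismatches. 42 families (tasiARF among them, 53 sequences) were listed by hand from textbook knowledge. 4 had no read and 37 passed the filter. A family is thus a set of reads that resemble a known microRNA, and precursors could not be checked without a genome.

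Differences were tested in edgeR 4.0.16 (R 4.3.3) with glmQLFit and glmQLFTest on 8 subregion means, for the families and for the 56069 single sequences that passed filterByExpr with a minimum count of 10. Library size was the total of the file times a TMM factor from the tested sequences. The p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, within each comparison. Comparisons were any difference among the subregions, filial against maternal, embryo proper against suspensor, embryo proper against endosperm, inner against outer integument, and each subregion against the mean of the other 7. The log2 fold change of an averaged comparison is a difference of mean logarithms over subregions. Shares of reads were compared among subregions by a two-sided permutation test of the F ratio with 100000 permutations, and between filial and maternal subregions by a two-sided exact permutation test of the 8 subregion means over the 56 splits. Family lists were tested with camera in limma 3.58.1 (preset correlation 0.01, and an estimated correlation beside it). Lengths and first bases of called sequences were compared by Fisher's exact test, adjusted over 96 tests. It counts sequences, which are not independent replicates, so its p-values do not measure the spread between libraries.

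Groups, tests, families, lists, the rule for named items and most alternatives were fixed before the data were examined. Families were named when called with at least 10 RPM on the higher side, up to 12 in each direction in the 4 main comparisons and up to 3 for each subregion. Sequences outside the families were named when called with at least 20 RPM on the higher side and every library of that side above every library of the other, up to 5 in each direction, by size of log2 fold change. The 10 most abundant families of a subregion could also be named. Where a group had 0 reads, the fold is a lower bound against 3 counts over the group, and with 1 to 3 reads the ratio is given with a 95% counting interval.

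The tests were tried on simulated data with the libraries' sizes and spread, in which 200 sequences were changed. In filial against maternal, 8.82% of the sequences changed 2-fold, 50% of those changed 4-fold and 89.4% of those changed 16-fold were recovered. The corresponding values were 0, 1.52% and 48.5% in embryo proper against suspensor, 0, 0 and 53.0% in embryo proper against endosperm, and 0, 4.55% and 56.1% in inner against outer integument. The 16-fold class was added after a simulation with the smaller folds alone had recovered few. Of 6 families changed 4-fold, 6, 2, 0 and 2 were recovered in these comparisons, and at most 6 unchanged sequences were called. In this simulation, 2 libraries per subregion thus missed most 4-fold changes and many 16-fold ones between pairs of subregions. It did not model sequences absent from a whole subregion. Of the 56069 tested in the real data, 39956 had 0 reads in at least 1 subregion, so its rates do not describe them.

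Alternatives fixed then were DESeq2 size factors, the DESeq2 test (version 1.42.0), file totals alone, family reads as library size, a replicate block, other low-count filters (a minimum count of 30, at least 20 reads in all, none for families), exact family matches only, only the libraries compared, subregion sums, distinct sequences in place of reads, reads of 20 to 24 nt only, and leaving out each library in turn. Alternatives added after the data were seen left out the 5 libraries with over 8 reads per distinct sequence, divided reads by the most frequent copy number of a library, allowed family starts within 3 bases, or left out sequences resembling 5S ribosomal RNA. The planned test of 24-nt reads in genome windows of 5000 bases, in 2 comparisons, was not run, since no genome was used here. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.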

Results

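Small RNAs of 18 to 26 nt were counted in 16 libraries from soybean (Glycine max, cultivar Williams 82) seeds at the heart stage, when the cotyledons of the embryo begin to form. Laser capture, which cuts chosen cells from tissue sections, separated 8 subregions with 2 libraries each. The embryo proper, the suspensor (the stalk that holds and feeds the young embryo) and the endosperm (the nourishing tissue from the other product of double fertilisation) are filial. The endothelium, inner integument, outer integument and epidermis, all layers of the seed coat, and the hilum, the region where the seed is attached, are maternal. The labels call the libraries of a subregion biological replicates but do not say which plants or seeds each came from, so the tests measure the spread between these capture pools. The libraries held between 2482688 reads (suspensor 1) and 6340013 reads (embryo proper 1). Levels are given in RPM, the usual scale of read counts relative to the library total, here the total of its 18 to 26 nt reads, with the SD of the 2 libraries. No genome came with the series, so sequences are given by their bases and have no coordinates or gene annotation.

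The number of distinct sequences ran from 196206 (suspensor 1) to 2019535 (embryo proper 1). Endothelium 1 and 2, epidermis 1 and 2 and suspensor 1 had between 8.67 and 14.5 reads per distinct sequence. The other 11 libraries had between 3.14 and 5.49. Reads outside 21, 22 and 24 nt, a sign of RNA breakdown among other things, made up 38.1% ± 4.68 of the endothelium reads, 35.3% ± 1.94 in the epidermis, 32.6% ± 5.57 in the suspensor and 31.7% ± 2.05 in the inner integument (SD, n = 2). They made up 19.9% ± 2.15 in the embryo proper.

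**Figure D1:**
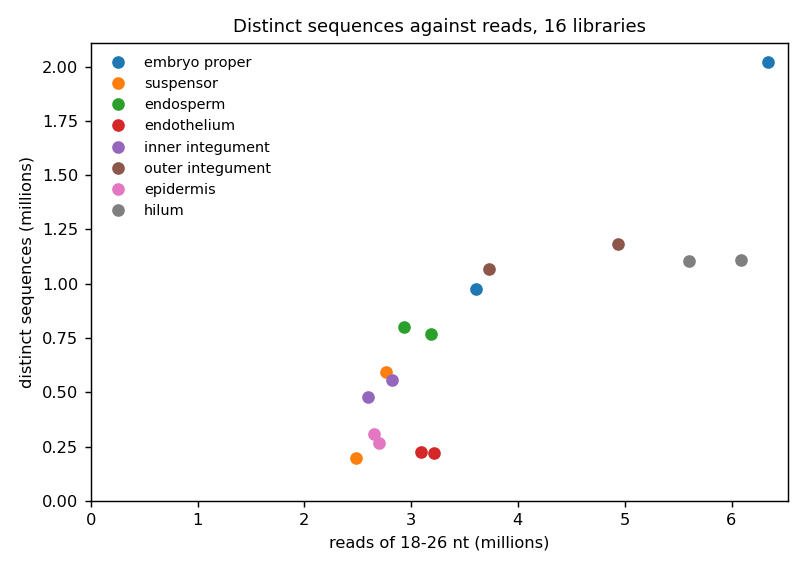
Distinct sequences (y axis, scaled as labelled) against reads of 18 to 26 nt (x axis, scaled as labelled) in the 16 libraries, 1 point per library, coloured by subregion. Endothelium 1 and 2, epidermis 1 and 2 and suspensor 1 lie lowest, with 196206 to 306135 distinct sequences.

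The length of a plant small RNA marks its kind: most microRNAs have 21 nt, and the small interfering RNAs that direct DNA methylation have 24 nt. Reads of 24 nt were most frequent in the embryo proper, at 51.7% ± 4.88 of reads, and in the outer integument, at 48.0% ± 2.56, and least frequent in the inner integument, at 30.2% ± 5.80 (SD, n = 2). The inner integument held the most 22-nt reads, 22.8% ± 5.52, and the embryo proper the fewest, 8.91% ± 0.784. Reads of 21 nt made up 27.6% ± 11.7 in the hilum, the highest mean, and 12.5% ± 2.37 in the suspensor, the lowest. The listed microRNA families took 22.6% ± 11.9 of reads in the hilum, 15.9% ± 0.574 in the embryo proper, 13.8% ± 1.66 in the inner integument and 4.83% ± 0.226 in the suspensor.

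The 8 subregions differed by more than their libraries in the 22-nt share (F ratio 5.70, permutation p = 0.00178, adjusted over the 5 shares 0.0089) and in the family share (F ratio 4.38, permutation p = 0.00397, adjusted 0.00992). The 21-nt share (F ratio 2.32, permutation p = 0.0306), the share of 24-nt reads in a library's 100 most abundant 24-nt sequences (F ratio 3.99, permutation p = 0.0428) and the 24-nt share (F ratio 3.61, permutation p = 0.0501) did not pass the correction, each with an adjusted p of 0.0501. The 21-nt share fell short even without correction in 14 of the 16 tests that left out 1 library (permutation p up to 0.125). The family share lost its call without embryo proper 1 (permutation p = 0.0543), embryo proper 2 (permutation p = 0.0552) or the 5 libraries with few distinct sequences (permutation p = 0.0770), a set chosen after the data were seen.

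Filial and maternal subregions did not differ in any of these shares by the exact permutation test of the 8 subregion means, 3 against 5. The 24-nt share averaged 43.9% in the filial and 36.8% in the maternal subregions (exact p = 0.232). The means were 13.0% and 15.2% for 22 nt (exact p = 0.571), 16.6% and 17.99% for 21 nt (exact p = 0.804), 8.58% and 11.7% for the families (exact p = 0.482), and 9.78% and 9.21% for the 100 most abundant 24-nt sequences (exact p = 0.839). The files came in 2 formats, with and without a header line, that may mark batches of processing. Content went with the format for 2 sequences, of 23 and 26 nt, called higher in the embryo proper than in the suspensor. Both had 0 RPM in every file with a header, and also in hilum 1, whose file has none. Inner integument 1, with a header, thus had 0 RPM of both, and inner integument 2, without, had 305 and 99.1 RPM. Whether reads were removed from files of either format was not tested. Among the 8 files with a header, 24-nt reads averaged 41.4% in 2 filial and 33.5% in 6 maternal libraries, and among the 8 without they averaged 45.2% in 4 filial and 41.8% in 4 maternal libraries. For 21 nt the filial mean was the lower in files with a header (12.5% and 19.1%) and the higher in files without (18.6% and 16.3%). The 22-nt means were 13.5% and 14.2% with a header and 12.8% and 16.6% without, and the family means 4.83% and 13.2% with and 10.5% and 9.49% without. For the 100 most abundant 24-nt sequences they were 10.3% and 10.4% with a header and 9.53% and 7.48% without.

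**Figure D2:**
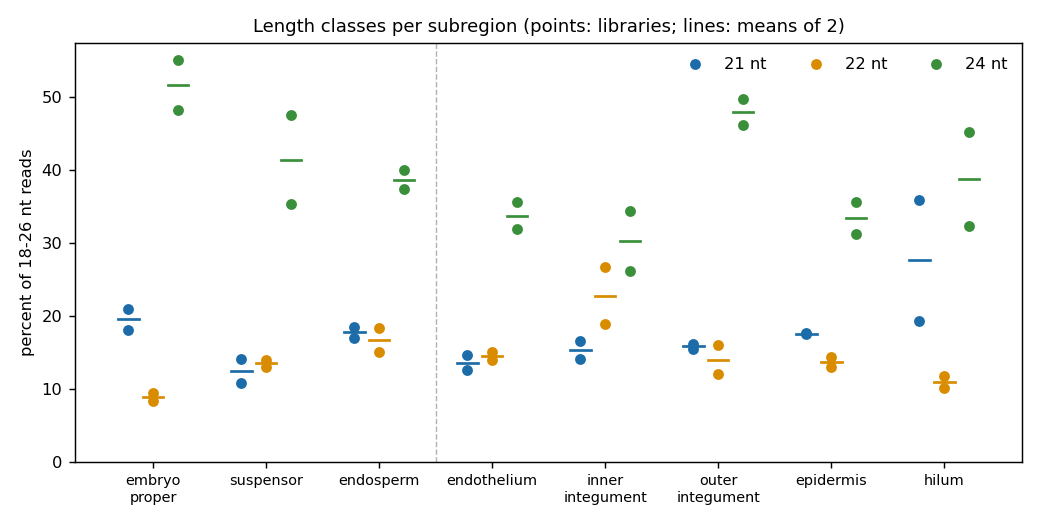
Percent of 18 to 26 nt reads (y axis) that had 21, 22 or 24 nt in each subregion (x axis, filial subregions left of the dashed line), with points for libraries and lines for means of 2. The embryo proper had 51.7% of reads at 24 nt on average and the inner integument 30.2%.

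The first base of a plant small RNA guides which Argonaute protein it joins, and 24-nt siRNAs that start with A are the typical partners of AGO4. In the inner integument 31.6% ± 0.773 of 24-nt reads started with A, against means of 46.2% (hilum) to 54.9% (suspensor) in the other 7 subregions. Counting each distinct sequence once gave 33.5% ± 0.441 against 43.9% (hilum 2) to 55.4% (suspensor 1) in the other 14 libraries. This measure was chosen after its values were seen.

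**Figure D3:**
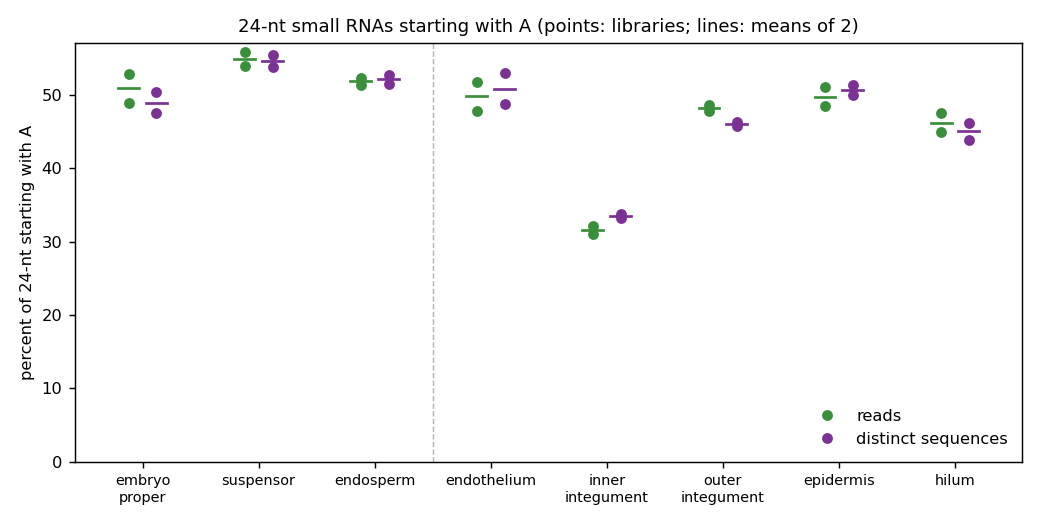
Percent of 24-nt small RNAs that start with A (y axis) in each subregion (x axis, filial subregions left of the dashed line), counted by reads and by distinct sequences, with points for libraries and lines for means of 2. The inner integument libraries lie lowest, at a mean of 31.6% of reads and 33.5% of distinct sequences.

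Of the 37 microRNA families tested, 36 differed among the 8 subregions (edgeR). miR165/miR166, which represses the class III HD-ZIP genes of organ polarity, had the highest mean of all families in each of the 8 subregions and reached 192131 ± 123691 RPM in the hilum and 114948 ± 5982 RPM in the embryo proper. In the inner integument it stood at 50324 ± 17728 RPM beside 43042 ± 5568 RPM of miR482, which targets NB-LRR disease resistance genes and which in inner integument 2 was the higher of the 2 (46979 and 37788 RPM). miR1507, another regulator of NB-LRR genes, ran from 2118 ± 375 RPM in the suspensor to 16476 ± 2488 RPM in the inner integument. Among single sequences, 31734 of the 56069 tested differed among the 8 subregions.

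**Figure D4:**
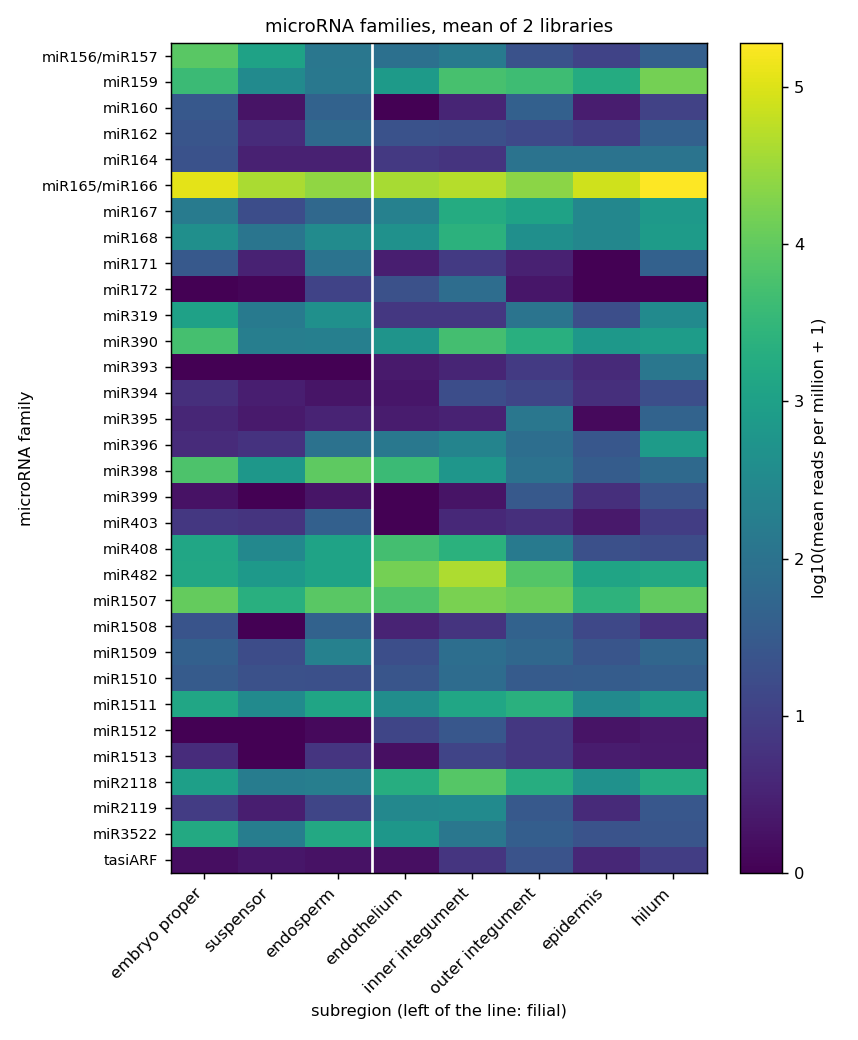
Level of microRNA families (rows) in the 8 subregions (columns, filial left of the white line), as the log10 of the mean RPM of 2 libraries plus 1. miR156/miR157 was highest in the embryo proper (8704 RPM) and miR393 in the hilum (123 RPM).

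The comparison of filial with maternal subregions asked which small RNAs separate the products of fertilisation from the tissues of the mother plant. miR156/miR157, which represses the SPL genes of phase change, averaged 3319 RPM in the filial and 61.5 RPM in the maternal subregions (log2 fold change 5.26, SE 0.42, adjusted p = 2.42e-14), with 8704 ± 2899 RPM in the embryo proper and 1129 ± 15.6 RPM in the suspensor (SD, n = 2). The filial endosperm, at 163 and 88.2 RPM, lay within the range of the maternal inner integument, at 221 and 77.5 RPM. The high level was thus that of the embryo proper and suspensor, not of all filial subregions. miR398, which targets copper superoxide dismutases, averaged 5419 and 942 RPM (log2 fold change 4.49), although the endothelium, a maternal layer, held 3920.2 ± 5067 RPM. The maternal mean was 225 RPM without endothelium 1 and 1658 RPM without endothelium 2. miR319, a regulator of TCP genes of leaf shape, averaged 543 and 93.5 RPM (log2 fold change 4.34), and miR3522, known mainly from legumes, 1117 and 165 RPM (log2 fold change 4.07), the latter 53.2 RPM without endothelium 1 and 277 RPM without endothelium 2. The maternal hilum, at 392 and 270 RPM, held more miR319 than the filial suspensor, at 137 and 167 RPM. In the other direction, miR393, which targets the auxin receptors TIR1 and AFB, had 0 filial reads and 1539 maternal reads, at least 292-fold lower in the filial subregions (floor of 3 counts over the group). Most of these reads came from hilum 1 (805) and hilum 2 (633), and without hilum 1 the bound was 166-fold. miR167, a regulator of auxin response factors, was lower in each of the 6 filial libraries than in each of the 10 maternal ones, with means of 76.7 and 817 RPM (log2 fold change -2.89).

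In all, 9 families were higher and 11 lower in the filial subregions (edgeR, 37 tested). Of the 14 families with 0 reads in some subregion, 7 were called and 5 had a p above 0.99 (edgeR). The absence of a call among these 14 therefore says little. miR2111 (log2 fold change -3.60), for example, had 0 filial reads and was not called. The families lower in the filial subregions also included miR482 (1107 and 13624 RPM, log2 fold change -2.00), miR2118, an NB-LRR regulator (439 and 2764 RPM, log2 fold change -2.06), miR396, a regulator of GRF growth factors (35.6 and 255 RPM, log2 fold change -2.98, the filial mean 19.7 RPM without endosperm 1), miR159, a regulator of GAMYB genes (1505 and 5513 RPM, log2 fold change -2.01), miR164, a regulator of NAC genes (8.03 and 64.3 RPM, log2 fold change -2.32), and miR2119 (7.16 and 137 RPM, log2 fold change -2.57). Higher families of low level were miR171, which represses GRAS genes (43.8 and 10.8 RPM, log2 fold change 3.70), miR403, which targets AGO genes (17.4 and 3.28 RPM, log2 fold change 3.55), and miR160, a regulator of auxin response factors (24.1 and 11.1 RPM, log2 fold change 2.66). The fitted value compares means of logarithms, so miR408, whose targets include copper proteins, was called higher in the filial subregions (log2 fold change 2.36) although its mean was 934 RPM there and 1556 RPM in the maternal subregions, where the endothelium held 5184 ± 5231 and the hilum 15.7 ± 2.82 RPM. This order of the means rests on endothelium 1, without which the maternal mean was 816 RPM.

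The filial and maternal groups were each mixed, and with each subregion summed to a single sample, 3 against 5, only miR156/miR157 (higher) and miR393 (lower) passed and miR408 turned to -0.02. The calls of miR160 (log2 fold change 1.05) and miR171 (1.66) ended without suspensor 2 and that of miR393 (-6.47) without endothelium 1, each of which left a subregion without reads of the family, and that of miR160 without the 5 libraries with few distinct sequences (0.39). With only reads identical to a listed family sequence, miR167 turned to 0.15 and lost its call, and miR160 lost its call (2.08, adjusted p = 0.0504). Such reads were 5.27% of the miR167 reads, whose most abundant sequence (20497 of 32420 reads) was not listed. They were 37.2% of the miR160 and 21.1% of the miR319 reads, so these values rest on a part of each family.

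Of the 56069 single sequences tested, 4696 were higher and 5808 lower in the filial subregions. With library sizes from file totals alone the split was 3392 higher and 9385 lower, and without the 5 libraries with few distinct sequences 25127 were called, which also removes the endothelium and epidermis, leaves 1 suspensor library and changes the filter, so the 2 counts do not compare like with like. Among those lower in the filial subregions 75.7% had 24 nt, against 58.0% of the other sequences tested (Fisher's exact test, adjusted p = 2.65e-158 over 96 tests, across sequences, which are not independent replicates). The tested sequences held from 37.6% of reads (suspensor 2) to 72.5% (inner integument 2), so they do not stand for all 24-nt reads. Of all reads, 43.9% in the filial and 36.8% in the maternal subregions had 24 nt, a difference in the other direction that did not pass. The 22-nt TTGGTTGTTCCTGGTAGGTGTC had 224 RPM in the filial and 1.20 RPM in the maternal subregions (log2 fold change 8.58, SE 0.41), and GGGGGCTTCAGAGTGATAGAACAGC 221 and 5.87 RPM (log2 fold change 5.95, SE 0.37). CTTGTGTCTCCCCTCTGGCCC had 1994 maternal reads and 0 filial reads, at least 378-fold lower in the filial subregions, and TCCGTGGACAAGGTGTTGGGCA had 66.1 RPM in the maternal and 0.773 RPM in the filial subregions. Of the 10504 calls, 2929 were among the 16113 sequences with reads in every subregion. Where a subregion had 0 reads its log mean has no lower limit, and 21107 of the other 39956 sequences had a p above 0.99, a bound set after the p values were seen, so the absence of a call among them says little.

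The embryo proper and the suspensor descend from the same zygote, and their comparison asked how the 2 parts of the embryo differ. miR390, which triggers the trans-acting siRNAs against auxin response factors, had 5319 ± 3260.4 RPM in the embryo proper and 177 ± 77.2 RPM in the suspensor (log2 fold change 5.30, SE 0.81, adjusted p = 2.59e-06). miR159 had 4047 ± 568 and 335 ± 233 RPM (log2 fold change 3.97), miR156/miR157 8704 ± 2899 and 1129 ± 15.6 RPM (log2 fold change 3.56), miR398 6332 ± 1318 and 638 ± 195 RPM (log2 fold change 3.78) and miR319 1036 ± 38.4 and 152 ± 21.4 RPM (log2 fold change 3.31). miR1508 had 215 reads in the embryo proper and 0 in the suspensor, at least 37.8-fold lower there. Bounds of this kind, here and below, fell by 1.57 to 2.76 times when 1 of the 2 libraries on the side with 0 reads was left out, as fewer reads then set the floor. In all, 21 of the 37 families were higher in the embryo proper and 0 lower. The 2 sides also differ in preparation: the suspensor libraries were made from 50 ng of RNA and their files have a header, the embryo proper libraries from 250 ng without, and reads of lengths other than 21, 22 and 24 nt made up 36.6% and 28.7% against 18.4% and 21.4%, so tissue and preparation are confounded in this comparison. The 2 single sequences named with the largest log2 fold changes (13.0 and 12.2) had 2137 and 1138 reads in the embryo proper and 0 in the suspensor. They also had 0 RPM in every other file with a header, so these calls cannot be told from an effect of file format.

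The families together took 15.9% ± 0.574 of reads in the embryo proper and 4.83% ± 0.226 in the suspensor. Relative to the reads of all families, 2 families, miR390 and miR1508, were called. The ratio of the library sizes moved by -2.35 (log2), the fitted log2 fold changes by other amounts (miR390 from 5.30 to 3.16), and miR156/miR157 (1.23), miR159 (1.85), miR398 (1.57) and miR319 (1.04) kept their sign without passing. miR165/miR166 (2.05) and miR482 (1.55), called higher in the embryo proper, came to -0.26 and -0.62. As miR165/miR166 supplies most family reads in both, its value near 0 follows from the scaling and says nothing about the family. The median of all tested sequences lay at 1.06 under the main scaling and at 0.43 with file totals alone. The suspensor libraries were uneven, with 196206 and 592172 distinct sequences.

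Among single sequences 1904 were higher in the embryo proper and 99 lower. The 5 sequences highest in the suspensor overlapped each other: TCTGTTGTGATTATTTGAAACATGGG had 585 reads there and 0 in the embryo proper, at least 370-fold higher in the suspensor, CTGTTGTGATTATTTGAAACATGGG 541 reads (at least 342-fold), and GTGAGTGTCTGTTGTGATTAT 338 reads (at least 214-fold, or 134-fold without suspensor 1). Of those lower in the embryo proper 11.1% had 24 nt, against 59.9% of the other sequences tested (Fisher's exact test, adjusted p = 1.97e-23). In the embryo proper CGACCGGGTATGAACATAGAAGAA had 389 reads against 0 in the suspensor, at least 68.4-fold higher. The count of sequences fell to 986 with file totals alone (670 higher, 316 lower), to 393 without suspensor 1, and rose to as many as 11164 without endothelium 1, where the filter then asks for enough reads in 1 library only and so tests more sequences, to 3197 with the replicate number as a block and to 3977 without the 5 libraries with few distinct sequences. GTGAGTGTCTGTTGTGATTAT lost its call without embryo proper 1 (log2 fold change -9.99, adjusted p = 0.0514) and by DESeq2 (-10.23, adjusted p = 0.262).

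The comparison of the embryo proper with the endosperm set the products of double fertilisation side by side. miR156/miR157 had 8704 ± 2899 RPM in the embryo proper and 126 ± 52.8 RPM in the endosperm (log2 fold change 5.60, SE 0.91, adjusted p = 8.36e-06). miR159 had 4047 ± 568 and 131 ± 35.8 RPM (log2 fold change 4.38) and miR390 5319 ± 3260.4 and 186 ± 61.6 RPM (log2 fold change 4.21). In the endosperm, miR396 was higher, with 98.3 ± 67.6 RPM against 3.53 ± 3.03 RPM (log2 fold change -5.21), and miR172, a regulator of AP2 genes, had 67 reads against 0 in the embryo proper, at least 36.3-fold higher (21.4-fold without endosperm 2). miR398 had 9286 ± 485 RPM there and 6332 ± 1318 RPM in the embryo proper and was not called.

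In all, 5 families were higher in the embryo proper and 5 lower, and relative to all family reads 3 were higher and 14 lower. The count fell to 5 without embryo proper 2 and to 6 without endosperm 2. miR165/miR166 (log2 fold change 1.65), miR2118 (1.81), miR1509 (-2.91) and miR403 (-3.21) lost their calls without endosperm 2 (1.23, 1.65, -2.43 and -2.88) or embryo proper 2 (1.92, 1.55, -2.39 and -2.34). miR165/miR166 also lost its call without embryo proper 1 (1.88), epidermis 1 or epidermis 2 (1.93 each) or the 5 libraries with few distinct sequences (1.92), miR1509 without embryo proper 1 (-2.90) or endosperm 1 (-2.93), and miR2118 (2.37) and miR403 (-3.15) without endosperm 1. miR2118 also lost its call with the replicate block (1.71, adjusted p = 0.0631), without the low-count filter (1.81, adjusted p = 0.0517) and relative to all family reads (0.73), and miR165/miR166 with only the libraries compared (1.65, adjusted p = 0.0546) and relative to all family reads (0.61).

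Single sequences were mostly higher in the endosperm, 11143 against 1783 higher in the embryo proper. Reads outside 21, 22 and 24 nt made up 26.5% and 27.2% in the endosperm libraries and 18.4% and 21.4% in those of the embryo proper. Whether this moved the calls was not tested. Of the sequences higher in the endosperm 19.6% had 21 nt, 20.1% had 22 nt and 41.5% had 24 nt, against 5.77%, 9.98% and 64.4% of the other sequences tested (Fisher's exact tests, adjusted p for 22 nt = 1.16e-168). The 24-nt AATGAACGCGGTCAACGGAGAAGT had 2342 endosperm reads and 0 in the embryo proper, at least 1268-fold higher, and ATACTTGCCCCTCCAAGACGTTGT had 1240 and 0, at least 671-fold higher. TCTCGGACCAGGCTTCATTCCT, which begins 2 bases before the usual miR166 start and was therefore not counted for that family, had 490 reads in the embryo proper and 0 in the endosperm, at least 101-fold higher. With file totals alone the split was 10326 higher in the endosperm and 3858 higher in the embryo proper. The count of 12926 fell to 1929 without embryo proper 1, 2922 without embryo proper 2, 4742 without endosperm 1 and 4930 without endosperm 2, and rose to 29129 without the 5 libraries with few distinct sequences.

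The inner and outer integument are the main layers of the young seed coat, and their comparison asked how far maternal layers differ. miR172 had 75.2 ± 11.9 RPM in the inner and 1.08 ± 0.767 RPM in the outer integument (log2 fold change 6.49, SE 1.22, adjusted p = 7.77e-05). miR408 had 2419 ± 749 and 143 ± 86.9 RPM (log2 fold change 4.57) and miR482 43042 ± 5568 and 7279 ± 3782 RPM (log2 fold change 3.04). The outer integument held more miR395, which acts in sulfate uptake, at 126 ± 52.2 against 2.22 ± 0.133 RPM (log2 fold change -5.34), more miR399, which acts in phosphate balance, at 29.3 ± 6.96 against 0.901 ± 0.729 RPM (log2 fold change -4.51), and more miR319, at 106 ± 23.2 against 6.11 ± 0.628 RPM (log2 fold change -3.63).

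In all, 13 families were higher in the inner integument and 7 lower. The counts were 8 and 7 with DESeq2 size factors or file totals and 3 and 10 relative to all family reads. Reads outside 21, 22 and 24 nt also separated the layers, at 30.2% and 33.1% in the inner and 22.0% and 22.3% in the outer integument. Whether this moved the calls was not tested. Only 9 families passed without inner integument 1 or without outer integument 1, 12 without inner integument 2, and 13 without epidermis 1 or epidermis 2. miR482 lost its call without outer integument 1 (log2 fold change 2.37, adjusted p = 0.0522), and miR319 with only reads identical to a listed sequence (-0.54). miR390, miR396, miR1512 and miR3522, called higher in the inner integument, lost their calls with DESeq2 size factors and in most fits that left out 1 library, and miR390 came to -0.09 relative to all family reads.

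Of the single sequences 39 passed, 35 higher in the inner integument and 4 lower, with 7444 at an unadjusted p under the threshold and 950 by DESeq2. The 21-nt GGAATGGGCTGATTGGGAAGC had 28124 RPM in the outer and 785 RPM in the inner integument (log2 fold change -4.70, SE 0.79, adjusted p = 0.0431). In the inner integument, 3 nested sequences ending in CTTTCTGAGGTTG were higher, of which TCTGCAATTCTGACTTTCTGAGGTTG had 723 reads against 3, a ratio of 385 (95% counting interval 131 to 1873). The nested ATTCTGACTTTCTGAGGTTG (428 reads against 4, adjusted p = 0.0548) and CTGCAATTCTGACTTTCTGAGGTTG (452 against 4, adjusted p = 0.0810) lost their calls without outer integument 1. The count was 17 without inner integument 1 or outer integument 1, 583 with the replicate block, 1150 without suspensor 1 and 3979 without the 5 libraries with few distinct sequences.

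Each subregion was also set against the mean of the other 7. The hilum stood out by miR393, with 123 ± 13.6 RPM (log2 fold change 8.37, SE 0.68, adjusted p = 2.12e-13) and at most 6.97 RPM in any other subregion, and by miR396, with 794 ± 495 RPM (log2 fold change 4.56). The inner integument was highest in miR172, with 75.2 RPM against a mean of 4.54 RPM in the other 7 (log2 fold change 7.70). It was also highest in miR1512, known mainly from legumes, with 26.4 ± 4.68 against 2.93 RPM (log2 fold change 5.61). The outer integument was highest in miR395 (log2 fold change 5.27) and miR399 (log2 fold change 4.99). The endosperm was highest in miR171, with 100.3 ± 4.59 RPM (log2 fold change 5.99), and miR398 (log2 fold change 5.52). For miR393, miR172, miR1512, miR399 and miR171, some of the other subregions had 0 reads. Their log means have no lower limit, so the size of these folds is not fixed. The mean of the other 7 was 2.02 RPM for miR393 (hilum), 4.08 RPM for miR399 (outer integument) and 12.2 RPM for miR171 (endosperm).

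The embryo proper was highest in miR156/miR157 (log2 fold change 7.25) and miR319 (log2 fold change 4.62). The suspensor was called higher in miR156/miR157 (log2 fold change 3.18). Its 1129 RPM nevertheless lay below the 1305 RPM mean of the other 7, which the embryo proper raises. It was lower in miR167, with 16.6 ± 16.0 RPM (log2 fold change -4.46). With only reads identical to a listed sequence, 5.27% of the family's reads, miR167 came to -1.31 and had no call. In the endothelium miR408 (log2 fold change 3.80) and miR2119, with 297 ± 46.9 RPM (log2 fold change 3.67), were higher. The inner integument held more miR2119, 330 RPM. The endothelium had 0 reads of miR160, at least 41.6-fold lower. The epidermis was higher than the mean of the other 7 in miR164, with 103 ± 10.6 RPM (log2 fold change 2.64). It was lower in miR408, with 18.3 ± 2.34 RPM (log2 fold change -5.35). Neither level was particular to it. The hilum libraries had 115 and 95.9 RPM of miR164 and the outer integument a mean of 102 RPM, and the hilum had 15.7 RPM of miR408. The 8 comparisons called 151 families together, 98 of them higher in the subregion, and 54040 single sequences, 47655 of them higher. miR164 in the epidermis lost its call without epidermis 1 (2.65, adjusted p = 0.0550) and miR160 in the endothelium (-7.39) without suspensor 2, which left the suspensor without reads of the family, and with only reads identical to a listed sequence (-5.30).

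Sequences higher in 1 subregion were most numerous in the endosperm, with 15449 higher and 852 lower, or 13043 and 2794 with file totals alone. The endosperm was marked by the 22-nt TTTGGATCAACGTTGGGAGAGT, with 433 RPM and 20 reads in all other libraries (log2 fold change 12.79). TCTGTTGTGATTATTTGAAACATGGG had 0 reads outside the suspensor, at least 1989-fold higher there. The epidermis was marked by TTTGATACACTAGTATGGATC (546 reads against 3 elsewhere, a ratio of 1813, 95% counting interval 617 to 8820) and the hilum by TGACCGTCGGAGCCTGCAAGTTGC (47.2 RPM, log2 fold change 7.92). Among the 24-nt sequences higher in the inner integument 30.9% started with A, against 57.0% of the other 24-nt sequences tested, and among those higher in the suspensor 74.8% against 52.1% (Fisher's exact tests, adjusted p = 2.99e-180 and 6.46e-149, across sequences, which are not independent replicates). These sequences were selected on the same reads as the shares starting with A given above, so they are no separate evidence for them.

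6 lists of families were fixed by their textbook targets. Between filial and maternal subregions, the nutrient list (phosphate, sulfate or copper) had 3 of 6 members higher and 0 lower. The lack of a call says little for miR399 (log2 fold change -2.57), with 0 reads in the suspensor and endothelium. It had at most 1.39 RPM in filial libraries and 15.4 to 34.3 RPM in those of the outer integument and hilum. The auxin list had 1 of 5 higher and 3 lower, the development list 4 of 12 higher and 5 lower. The NB-LRR list had 0 of 4 higher and 2 lower, the legume list 1 of 11 higher and 2 lower, and the silencing list 1 of 3 higher and 0 lower. In the embryo proper against the suspensor, 8 of 12 development, 6 of 11 legume and 3 of 5 auxin families were higher. So were 3 of 4 NB-LRR, 2 of 6 nutrient and 2 of 3 silencing families, and 0 were lower. Relative to all family reads only miR390 and miR1508 were called in this comparison. That scaling takes out any shift shared by the families, so it cannot show whether such a shift was real. The named families of this comparison kept their calls with DESeq2 size factors and with file totals. Against the endosperm, 3 development families were higher and 2 lower, 1 auxin and 1 NB-LRR family higher, 2 legume families and 1 silencing family lower, and 0 nutrient families called. In the inner against the outer integument 4 development families were higher and 3 lower, 2 nutrient higher and 3 lower, 3 legume higher and 1 lower, 2 NB-LRR higher, 1 silencing higher, and 1 auxin higher and 1 lower.

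As a set, 0 of the 24 combinations of list and comparison passed camera at an adjusted p under the threshold, with the preset or an estimated correlation, and 0 at an unadjusted p under the threshold. The smallest p was 0.0962, for the legume list against the endosperm (p = 0.201 with an estimated correlation). The lists hold 3 to 12 families. With p adjusted over the list alone the counts changed in 5 of the 24: development 4 higher and 6 lower between filial and maternal subregions and 4 higher and 3 lower against the endosperm, legume 7 higher against the suspensor, NB-LRR 0 against the endosperm, and nutrient 3 higher and 3 lower between the integuments. The direction of the set test had another sign than the list's median for the legume list between filial and maternal subregions, the nutrient list against the suspensor and the development list between the integuments, and another sign than the mean for the development list against the endosperm.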

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

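The measures in this part and the tests of depth and RNA input were chosen only after the result was seen, while the draws by copy number and the splits of the subregions were set beforehand. 3 signals lay outside the listed families and were picked for their large share of reads, with no control samples to set them against, so the shares show only that they are abundant. Sequences containing GTCCTCGTGTTGCACC, a stretch of plant 5S ribosomal RNA, made up 21.3% of reads in the inner integument (SD 9.82, n = 2), 17.99% ± 2.64 in the epidermis, 17.8% ± 0.385 in the endothelium and 4.70% ± 2.67 in the embryo proper. TCTCGGACCAGGCTTCATTCC, which begins 2 bases before the usual miR166 start and was therefore not counted for the family, made up 4.12% of reads in the outer integument (SD 0.592, n = 2), 2.37% ± 0.246 in the embryo proper and 0.0208% ± 0.00296 in the endosperm. In the inner integument it made up 0.689% and 0.405%. The call of miR165/miR166 as higher in the inner than in the outer integument (log2 fold change 1.60) was made without these reads and so depends on the rule for starts. GGAATGGGCTGATTGGGAAGC made up 2.81% of reads in the outer integument (SD 0.119, n = 2), 2.08% ± 0.492 in the epidermis and 0.0256% ± 0.0218 in the suspensor.

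Endothelium 1 and 2, epidermis 1 and 2 and suspensor 1 held few distinct sequences. Depth alone does not account for this: after drawing 2400000 reads from each library the highest of the 5 had 301024 distinct sequences and the lowest of the other 11 had 458674. The stated RNA input is not the whole cause either, since 2 of the 5 libraries, those of the epidermis, were made from 250 ng. PCR copies of few starting molecules remain a candidate explanation: a sequence was most often seen 5 times in both endothelium libraries, 6 times in suspensor 1, 3 times in epidermis 1 and 2 times in epidermis 2, but also 2 times in suspensor 2, which is not among the 5. Drawing from libraries with a most frequent copy number of 1 as few reads as that implies gave ratios of distinct sequences of 0.988 or more. A true difference between these tissues in the variety of small RNAs was not tested and stays open.

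The families called between filial and maternal subregions cannot be set apart from chance groupings of the subregions: 19 of the 56 splits into 3 and 5 called as many families as the real 20. The highest other split, endothelium, epidermis and suspensor against the rest, called 31 and follows the subregions of the 5 libraries with few distinct sequences. For single sequences 5 of the 56 splits called as many as the real 10504, and the highest other split, with hilum, inner and outer integument against the rest, called 11644. The subregions differ among themselves, so that some splits which join other subregions also call many sequences, while others call almost none.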

How the results depend on the processing

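Leaving out the 5 libraries with few distinct sequences, dividing reads by copy number, family starts within 3 bases and leaving out 5S-like sequences were chosen after the data were seen, and all other alternatives beforehand. Of the values of named families under the alternatives, 2308 kept direction and side of the threshold, 165 lost the call and 4 reversed. Of those of named sequences 1257 kept both and 23 lost the call. The causes of the shifts below were not tested unless stated. The scalings moved the ratio of library sizes in a comparison against TMM (log2), and the fitted log2 fold changes by amounts that differed between families: DESeq2 size factors by -0.24 (filial against maternal), -0.22 (embryo proper against suspensor), 0.14 (against endosperm) and -0.48 (integuments), file totals by -0.52, -0.63, 0.57 and -0.47, and family reads by -0.03, -2.35, -1.13 and -1.78. None of the 24 list tests passed under any alternative run. The genome window tests and their alternatives were not run. With 2 libraries per subregion, the pairwise tests recovered few simulated 4-fold changes of sequences and 48.5% to 56.1% of the 16-fold ones.

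For families, taking family reads as library size gave 2 calls for embryo proper against suspensor, 17 against endosperm and 13 between the integuments, and subregion sums gave 2 between filial and maternal. Reversed, each without a call, were miR390 between the integuments with family reads (-0.0892), miR167 filial against maternal with exact matches (0.15), miR171 in the epidermis with starts within 3 bases (1.31) and miR408 filial against maternal with subregion sums (-0.0234). For single sequences, DESeq2 size factors gave 61 calls between the integuments and file totals 986 for embryo proper against suspensor. The replicate block gave 3197 for embryo proper against suspensor and 583 between the integuments. A minimum count of 30, which tests fewer sequences, gave 12254 for any difference, 5767 filial against maternal, 6804 against endosperm, 656 between the integuments and 24924 for the single subregions. At least 20 reads in all, which tests more, gave 61349 for any difference, 3757 against suspensor, 331 between the integuments and 136097 for the single subregions. Reads divided by copy number gave 3670 against suspensor and 2447 between the integuments. Without the 5 libraries, which removes the endothelium and epidermis, leaves 1 suspensor library and changes the filter, the counts were 25127 (filial against maternal), 3977 (suspensor), 29129 (endosperm) and 3979 (integuments). The DESeq2 test gave 17393 for any difference, 3902 (suspensor), 4319 (endosperm), 950 (integuments) and 30217 for the single subregions.

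Counting distinct sequences reversed the filial minus maternal difference of the 21-nt share to 0.359 and of the 22-nt share to 2.06 points, neither past the exact permutation test. The 21-nt F ratio was 1.90 with reads of 20 to 24 nt only (permutation p = 0.0773) and 1.82 without the 5 libraries (p = 0.150). The p values of this part are not adjusted over the 5 shares, unlike those of the report. The 24-nt F ratio had a p under the threshold with a replicate block (4.10, permutation p = 0.0384) and with distinct sequences (10.9, p = 0.00634). The family share was over it without the 5 libraries (3.35, permutation p = 0.0770).

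Leaving out each library in turn, which assumes that the lone library of a subregion varies like the others and lets the filter test more sequences, gave these ranges. Families: any difference 36 to 38, filial against maternal 18 to 23, suspensor 20 to 27, endosperm 5 to 12, integuments 9 to 22, single subregions 142 to 166. Single sequences: any difference 32982 to 60231, filial against maternal 8233 to 15142, suspensor 393 (without suspensor 1) to 11164, endosperm 1929 (without embryo proper 1) to 19708, integuments 17 to 1150, single subregions 65559 to 118542. F ratios: 21 nt 1.82 to 27.7, 22 nt 4.25 to 14.1, 24 nt 2.42 to 5.18, families 3.59 to 110.2, the 100 most abundant 24-nt sequences 2.93 to 14.2. Filial minus maternal: 21 nt -3.07 to 0.232 (reversed without hilum 2), 22 nt -2.93 to -1.37, 24 nt 5.07 to 9.11, families -4.79 to -1.43, the 100 most abundant -0.853 (reversed without suspensor 1) to 1.99 points. By unadjusted permutation p, the 24-nt share was under the threshold without suspensor 1, suspensor 2, hilum 1 or hilum 2, the 21-nt share without hilum 1 or hilum 2 only, and the 100 most abundant in 3 of the 16.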

Other observations

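In this part, the tests of abundant sequences, of ligation bias, of few starting molecules and of few distinct sequences in the libraries compared were chosen only after the result was seen, and those of breakdown, of PCR copies in the endosperm and of scaling beforehand. The suspensor had the highest share of 22 nt among its distinct sequences, 12.5% ± 2.19 against 5.36% ± 0.0750 in the embryo proper, and 42.8% ± 4.02 of these began with T, against 29.97% ± 0.00184 in the embryo proper and 35.1% ± 0.251 in the endosperm (SD, n = 2). The 1000 most abundant 24-nt sequences took 29.6% ± 1.46 of 24-nt reads in the endosperm and 9.09% ± 2.10 in the embryo proper. A group of 6152 24-nt sequences called higher in the endosperm than in the other 7 subregions took 15.7% of the reads of each endosperm library and 1.29% to 3.62% in the other libraries, as values of sequences selected on these data. Replicates of single sequences correlated with Spearman's rho between 0.593 (endothelium) and 0.846 (endosperm), across sequences, which are not independent replicates. In families the 2 endothelium libraries agreed less with each other (0.911) than endothelium 2 did with inner integument 2 (0.937). In sequences they agreed hardly more (0.593) than an endothelium library with inner integument 2 (0.562). The same held for the epidermis libraries in sequences, at 0.6755 with each other and 0.6585 between an epidermis library and hilum 1.

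Few 24-nt small RNAs began with A in the inner integument. A few abundant sequences do not account for it, since at most 33.8% of distinct 24-nt sequences began with A there and at least 43.9% in the other libraries. A bias of 5 prime adapter ligation would also lower other lengths. Of distinct 22-nt sequences 26.4% began with A there, above both suspensor libraries (15.0% and 17.2%) and just below epidermis 1 (26.5%). Of distinct 21-nt sequences 25.6% and 25.8% did, inside the range of the others (18.3% to 30.4%), and of 21-nt reads 24.4% and 26.6%, above all others (up to 21.7%). The bound first set, on 21 and 22 nt alone, would exclude the bias. The neighbouring lengths, added to the test later, go with it, with 31.0% and 31.4% at 25 nt against at least 35.0% elsewhere and 28.9% and 29.3% at 23 nt against at least 30.4%, so it stays open. For breakdown fragments of random start, the neighbouring lengths were subtracted, after which at most 34.3% began with A, against at least 44.5% elsewhere. This outcome was fixed by the numbers subtracted. Inner integument 1 had 49482 and 30448 distinct sequences of 23 and 25 nt beside 336913 of 24 nt. Inner integument 2 had 41982 and 26966 beside 275597. Removing so few could not lift the share to 44.5%, whatever their first bases. Fragments as numerous as these are thus too few to account for the low share, but larger numbers at 24 nt were not tested. Another mix of 24-nt siRNAs in this layer is also open and was not tested.

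Many more sequences were higher than lower in the endosperm against the other 7 subregions, at 15449 and 852. This excess alone does not set it apart. It was relatively larger in the inner integument (6241 and 153), embryo proper (5211 and 202), hilum (5086 and 206) and outer integument (5234 and 228). It was smaller in the endothelium (3332 and 728), epidermis (2091 and 502) and suspensor (5011 and 3514). What set the endosperm apart was the number higher, the largest of all subregions. The 844 of the 1000 most abundant 24-nt sequences of endosperm 1 that were among the 1000 of endosperm 2 do not decide on PCR copies of a few molecules, since the endothelium (685), epidermis (714) and suspensor (617), where sequences were most often seen more than once, also pass the bound of 500 set beforehand. Few starting molecules in the endosperm libraries are argued against, since sequences seen once were 3.25 and 3.97 times those seen 2 times, against at most 2.48 times in the other libraries. Few distinct sequences in the libraries compared cannot be the whole cause, since 11143 were higher than in the embryo proper, whose libraries held more distinct sequences, and 1783 lower. The share due to TMM scaling stays open. With file totals alone 13043 were higher and 2794 lower. This leaves an excess but misses the bound of over 5 times set beforehand. Such an excess is not particular to the endosperm under this scaling either. The outer integument had 9467 higher and 162 lower and the hilum 4349 and 224. Only the suspensor, with 6457 and 2931, had a relatively smaller excess than the endosperm. The number higher stayed the largest in the endosperm. A difference of the tissue itself remains a possible explanation of the number higher and was not tested on other samples.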
